A study of Populus trichocarpa with 12 samples.

How the data were processed

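RNA was sequenced from differentiating xylem, the young wood scraped from debarked stems of greenhouse-grown Populus trichocarpa (black cottonwood). The 12 libraries form 3 groups of 4, sampled after 0, 5 and 7 days without watering. Replicate numbers and groups were taken from the library titles. Soil and xylem water contents are those given in the labels, 1 value per group, with no spread.

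The authors deposited 1 table of whole-number read counts for 41335 gene identifiers in the 12 libraries, with no normalisation. Reads were processed with TopHat, per the submitters' processing notes; its version, the genome build, the counting program and whether counting used strand are not given in the sources used here. Libraries followed standard Illumina protocols, per the labels' protocols. Whether reads from overlapping or antisense genes were kept apart is therefore not known, and reads from near-identical gene copies can be split among them or counted for each. The table holds signs of the latter, since 103 tested genes have counts identical to those of another tested gene in all 12 libraries, in 39 sets of up to 10 genes. None of the wood genes described in the report is among them, which does not exclude reads shared between similar wood genes. Every row of the table names a gene, and all 12 count columns were used.

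Total counts ranged from 9.35 to 19.22 M per library. A mean of 0 in a group was treated as at most 3 counts over the 4 libraries, which is 0.0541 CPM (counts per 1 M scaled counts) on day 0, 0.0486 on day 5 and 0.0558 on day 7, and the other group's mean CPM was divided by it. Such bounds and the 95% binomial (Clopper-Pearson) intervals of count ratios cover counting error only. No pair of libraries within a group agreed within sampling noise: chi-square per degree of freedom lay between 12.25 and 94.14.

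Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, which left 26943. Library sizes were scaled by TMM. A quasi-likelihood model with 1 mean per group was fitted to all 12 libraries (glmQLFit, glmQLFTest), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Standard errors were taken as the log2 fold change over the square root of F. Log2 CPM used a prior count of 2. Gene lists were tested with fry from limma 3.58.1, which asks whether the members move on balance in 1 direction (adjusted over 9 tests, the list and its 2 parts in 3 comparisons), and with camera at a preset correlation of 0.01 and at an estimated correlation. Each list's median was also placed among 10000 random lists of the same size matched on mean expression. Values per library were compared with two-sided exact permutation tests, for which 4 against 4 libraries give at best p = 0.0286. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

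The tests were tried on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. So few changed genes make the adjusted threshold stricter than in the data, where far more genes were called. The recovered shares therefore do not carry over to the comparisons below. edgeR recovered 36% of the 2-fold and 78% of the 4-fold changes for day 5 against day 0, 22% and 82% for day 7 against day 0, and 31% and 81% for day 7 against day 5, with 4, 7 and 0 false calls. DESeq2 recovered more 2-fold changes (61%, 66% and 62%) with 70, 71 and 74 false calls, and limma-voom recovered 34%, 23% and 30% with 4, 4 and 2.

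Designs, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined; the parts of the wood list, its share of counts and the return of day 5 changes were added afterwards. Of the gene lists, 26 were defined by product names. Neither the count table nor the RefSeq gene table used here pairs any of the 41335 identifiers with a name, so those 26 lists were not analysed here. The remaining list, fixed by identifier for this case, holds 24 genes known from published designations as wood synthases: 19 enzymes of monolignol synthesis and 5 cellulose synthases. The enzyme family of each identifier was assigned from those designations after the data were seen and is not given by the files. Without names, the rule names at most 2 identifiers per direction and comparison: those with the largest log2 fold change among genes with adjusted p under 0.05, a mean of at least 5 CPM in the higher group and no overlap between the 4 libraries of each group. Added to these are the 2 members of the wood list with the smallest adjusted p on day 7.

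Alternatives were RLE and upper-quartile scaling, no or a stricter low-count filter (1 CPM in 4 libraries), DESeq2 1.42.0, limma-voom, a test against a minimum fold of 2, the 2 compared groups alone, replicate number as a block, each library left out in turn, and the camera tests. The overlap of both days was recomputed with the day 0 libraries split 2 and 2 and in 20 simulated data sets without effects. Labels do not say that replicates came from separate trees, so p-values measure only the spread between these libraries, which may be partly technical.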

Results

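Transcript levels were measured by RNA-seq in stem differentiating xylem of Populus trichocarpa at 3 points of a drought treatment. The 4 day 0 libraries came from fully irrigated plants, with soil at 74% and xylem at 80.6% water. After 5 days without watering, described as mild drought, soil held 33% and xylem 75.3% water. After 7 days, described as severe drought, these were 29% and 74.3%. Total counts averaged 13.3 M ± 2.81 (SD, n = 4) on day 0, 15.4 M ± 2.96 on day 5 and 14.2 M ± 2.36 on day 7. Watered plants sampled on days 5 and 7 were not analysed here, so days of drought coincide with plant age and day of harvest in each comparison.

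Libraries of each day stood apart from those of the other days. The first principal component held 60.5% of the variance and placed all 4 day 0 libraries between -204 and -168, and all day 5 and day 7 libraries between 17.9 and 125. The second component, with 20.9%, placed the day 5 libraries between -122 and -70.1 and the day 7 libraries between 55.3 and 132. Day 7 replicate 2 was the drought library nearest to day 0 on the first component.

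**Figure D1:**
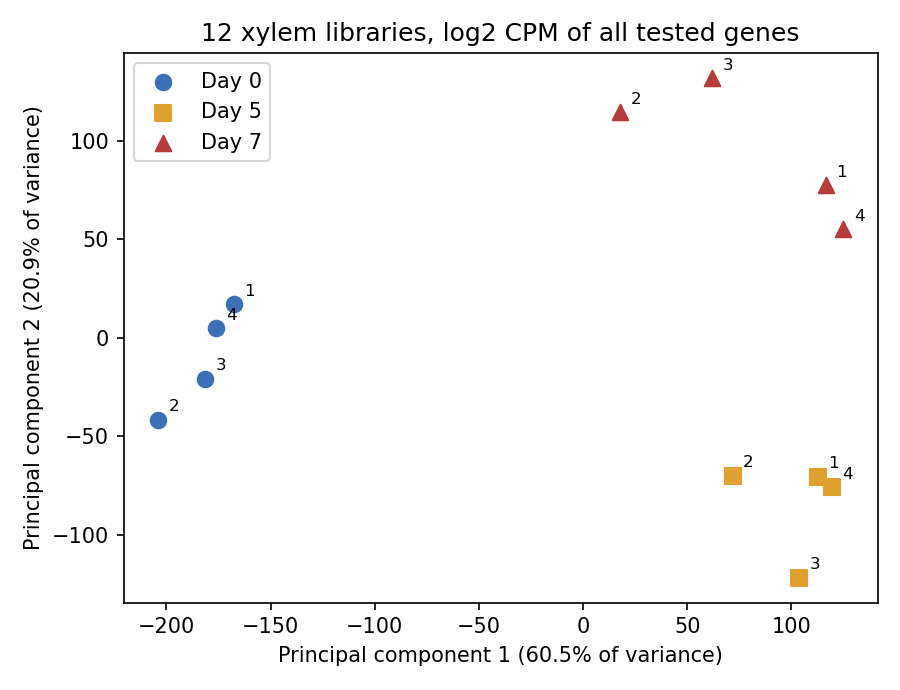
Principal components 1 and 2 of log2 CPM over the 26943 tested genes, 1 point per library, numbered by replicate and coloured by day. The first component, with 60.5% of the variance, parts day 0 from both drought days, and the second, with 20.9%, parts day 5 from day 7.

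The first comparison asked what mild drought changed in xylem. Genes of wood formation fell: of the 24 genes of the wood list, 18 were lower on day 5, and the other 6 were not called. Adjusted over the list alone, 19 were lower. Every member had a negative log2 fold change, from -2.43 to -0.55, with a median of -1.81, or 3.51-fold lower. These values lean on day 0 replicate 2, which had the largest wood share of that day. Without it, 14 genes were called lower and the median was -1.32, with an unadjusted fry p of 0.0238 for the list. Among the 19 genes for enzymes of monolignol synthesis, which makes the precursors of lignin, 15 fell and the median was -1.25. Of the 5 cellulose synthase genes, 3 fell and the median was -2.04.

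Family medians along the monolignol pathway lay between -2.36 and -0.73 on day 5, with no test between families. All 4 called genes among the 5 for phenylalanine ammonia-lyase, the entry enzyme of the phenylpropanoid pathway, were lower, with a family median of -2.09. Potri.010G224100 and Potri.010G224200 of this family changed nearly alike, by -2.11 and -2.09, so reads shared between them were not excluded. Both cinnamate hydroxylase genes fell, with a median of -2.33. Both hydroxycinnamoyltransferase genes (-1.63) and both coumarate-CoA ligase genes (-1.24) fell as well. The cinnamoyl-CoA reductase gene, at -0.73, did not pass the test. Potri.012G006400, published as a caffeic acid methyltransferase, went from 2626 CPM ± 1769 (SD, n = 4) on day 0 to 512 CPM ± 177 on day 5, a log2 fold change of -2.36 ± 0.46 (SE; edgeR adjusted p = 0.00118). Potri.019G130700, published as a cinnamate hydroxylase, went from 1204 CPM ± 560.3 to 256 CPM ± 80.6, a log2 fold change of -2.23 ± 0.41 (SE; edgeR adjusted p = 0.000736).

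The wood list took 2.44% ± 1.18 (SD, n = 4) of normalised counts on day 0 and 0.790% ± 0.213 on day 5 (exact permutation p = 0.0286, the smallest possible; 0.0321 adjusted over 18 such tests). Without any 1 of the day 5 libraries this exact p was 0.0857. The fry test of limma gave adjusted p = 0.00854 for the list (0.00759 unadjusted), adjusted p = 0.00775 for the monolignol genes (0.00603) and adjusted p = 0.0282 for the cellulose synthase genes (0.0282). Set against other genes by camera, the list had p = 8.3e-05 at the preset correlation and p = 0.294 with an estimated correlation, and the monolignol genes had p = 0.000264 and p = 0.277. For the cellulose synthase genes camera gave p = 0.072 at the preset and p = 0.404 with an estimated correlation, and fry lost the call without day 0 replicate 2 (p = 0.077), day 0 replicate 3 (p = 0.0584), day 5 replicate 1 (p = 0.0527) or day 5 replicate 4 (p = 0.0842). None of 10000 matched random lists had a median as low as that of the wood list. Their genes were drawn singly, without the correlation between wood genes (estimated at 0.626), so their medians spread less. The random lists therefore cannot decide whether a list of such correlated genes would fall this far by chance.

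Over all genes, 15807 of 26943 (58.7%) changed between day 0 and day 5, with 8046 higher and 7761 lower (7354 and 8555 with upper-quartile scaling). Of these, 5119 were at least 2-fold higher and 4755 at least 2-fold lower by point estimate; tested against a minimum fold of 2, 3367 were higher and 2695 lower. Potri.006G122400 had no count on day 0 and 83.1 CPM ± 73.7 (SD, n = 4) on day 5, at least 1535-fold higher (at least 875-fold without day 5 replicate 1; edgeR adjusted p = 0.000771). Potri.001G173000 also had no count on day 0 and reached 49.3 CPM ± 34.1, at least 910.3-fold higher (at least 605-fold without day 5 replicate 4; edgeR adjusted p = 0.000515). Potri.004G019400 went from 13.3 CPM ± 1.55 to no count, at least 274-fold lower (edgeR adjusted p = 1.01e-05). Potri.006G106900 went from 11.7 CPM ± 6.36 to no count, at least 239.8-fold lower (edgeR adjusted p = 5.66e-05). In all, 65 changed genes without a count on day 0 averaged at least 5 CPM on day 5, and 3 changed genes with at least 5 CPM on day 0 had no count on day 5.

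The second comparison set severe drought against full irrigation. All 24 genes of the wood list were lower on day 7, with log2 fold changes from -5.76 to -1.74 and a median of -3.56, or 11.8-fold lower. The 19 monolignol genes had a median of -3.19, or 9.11-fold lower. The 5 cellulose synthase genes had a median of -4.48, or 22.3-fold lower; it was -3.84 without day 0 replicate 2 and -5.28 without day 7 replicate 2. Among the monolignol families, the cinnamate hydroxylase genes had the lowest median (-4.64), followed by the caffeic acid methyltransferase gene (-4.47), and the cinnamyl alcohol dehydrogenase gene had the smallest change (-1.74).

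Potri.012G006400 was at 118 CPM ± 37.7 (SD, n = 4) on day 7, a log2 fold change of -4.47 ± 0.51 (SE; edgeR adjusted p = 4.13e-05). Potri.019G130700 was at 85.8 CPM ± 35.6, a log2 fold change of -3.81 ± 0.43 (SE; edgeR adjusted p = 4.22e-05). The wood list took 0.266% ± 0.137 (SD, n = 4) of normalised counts on day 7 (exact permutation p = 0.0286 against day 0; 0.0321 adjusted over 18 tests). By limma's fry test the list had adjusted p = 8.28e-05 (1.84e-05 unadjusted), the monolignol genes adjusted p = 8.28e-05 (1.35e-05) and the cellulose synthase genes adjusted p = 0.000348 (0.000116). With an estimated correlation, camera gave p = 0.0704, p = 0.0643 and p = 0.125, against p = 4.27e-13, p = 3.09e-11 and p = 0.000526 at the preset correlation.

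**Figure D2:**
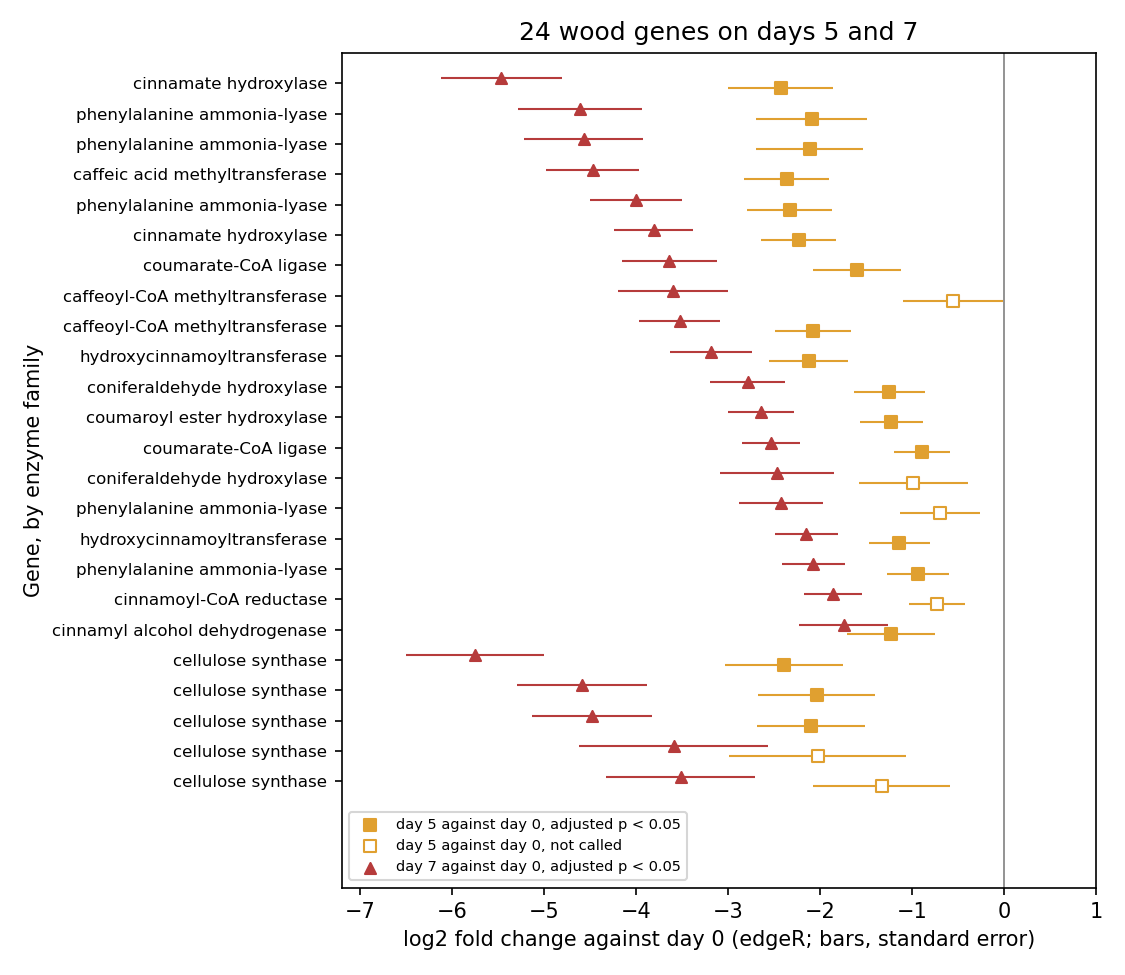
Log2 fold change against day 0 of each of the 24 wood genes on days 5 and 7, labelled by enzyme family, with bars of 1 standard error; filled points had an edgeR adjusted p under 0.05. All 24 were called lower on day 7 and 18 on day 5.

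Over all genes, 13761 of 26943 (51.1%) changed between day 0 and day 7, with 7402 higher and 6359 lower (6686 and 7041 with upper-quartile scaling). Against a minimum fold of 2, 3197 were higher and 2426 lower. Potri.004G180200 had no count on day 0 and 66.5 CPM ± 64.3 (SD, n = 4) on day 7, at least 1228-fold higher (at least 712-fold without day 7 replicate 3; edgeR adjusted p = 0.00212). Potri.004G180000 had no count on day 0 and 62.3 CPM ± 63.6, at least 1151-fold higher (at least 625-fold without day 7 replicate 3; edgeR adjusted p = 0.00248). Day 7 replicate 2 held only 0.478 CPM of each of these 2 genes, against 31.3 to 150 CPM in the other day 7 libraries. The bounds therefore rest on those other libraries. The levels of this pair were close to each other in every library, so reads shared between them were not excluded. By limma-voom neither was called (adjusted p = 0.167 and 0.16). Potri.018G082600 went from 8.83 CPM ± 3.86 to no count, at least 158-fold lower (edgeR adjusted p = 0.000297), and Potri.005G013000 from 8.23 CPM ± 2.90 to no count, at least 148-fold lower (edgeR adjusted p = 3.32e-05). In all, 47 changed genes without a count on day 0 averaged at least 5 CPM on day 7, and 8 changed genes with at least 5 CPM on day 0 had no count on day 7.

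The third comparison tested directly whether severe and mild drought differed. Wood genes were lower again on day 7 than on day 5: 20 of the 24 fell between these days (22 adjusted over the list alone), with log2 fold changes from -3.36 to -0.51 and a median of -1.66, or 3.15-fold lower. Of the monolignol genes 16 of 19 fell, with a median of -1.58, and of the cellulose synthase genes 4 of 5, with a median of -2.38 (-3.63 without day 7 replicate 2). Among the largest median changes of monolignol families were those of the cinnamate hydroxylase genes (-2.31) and the caffeoyl-CoA methyltransferase genes (-2.25). The cinnamyl alcohol dehydrogenase gene, at -0.51, did not pass the test. Potri.012G006400 fell by 2.11 on the log2 scale (SE 0.46; edgeR adjusted p = 0.00397) and Potri.019G130700 fell by 1.58 (SE 0.40; edgeR adjusted p = 0.00871).

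For day 7 against day 5, limma's fry test gave adjusted p = 0.0017 for the list (0.000942 unadjusted), adjusted p = 0.0017 for the monolignol genes (0.000851) and adjusted p = 0.00357 for the cellulose synthase genes (0.00238). Here camera gave p = 0.126, p = 0.122 and p = 0.18 with an estimated correlation. Day 7 replicate 2 held more wood transcripts than the other day 7 libraries, with cellulose synthase genes at a mean log2 CPM of 6.80 against 4.09 to 4.22. Cellulose synthase genes took 0.0288% ± 0.0355 (SD, n = 4) of normalised counts on day 7 and 0.140% ± 0.0680 on day 5 (exact permutation p = 0.0571). For the whole list the exact permutation p was 0.0286, and 0.0571 without day 5 replicate 2 or 3 or without day 7 replicate 1, 3 or 4.

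**Figure D3:**
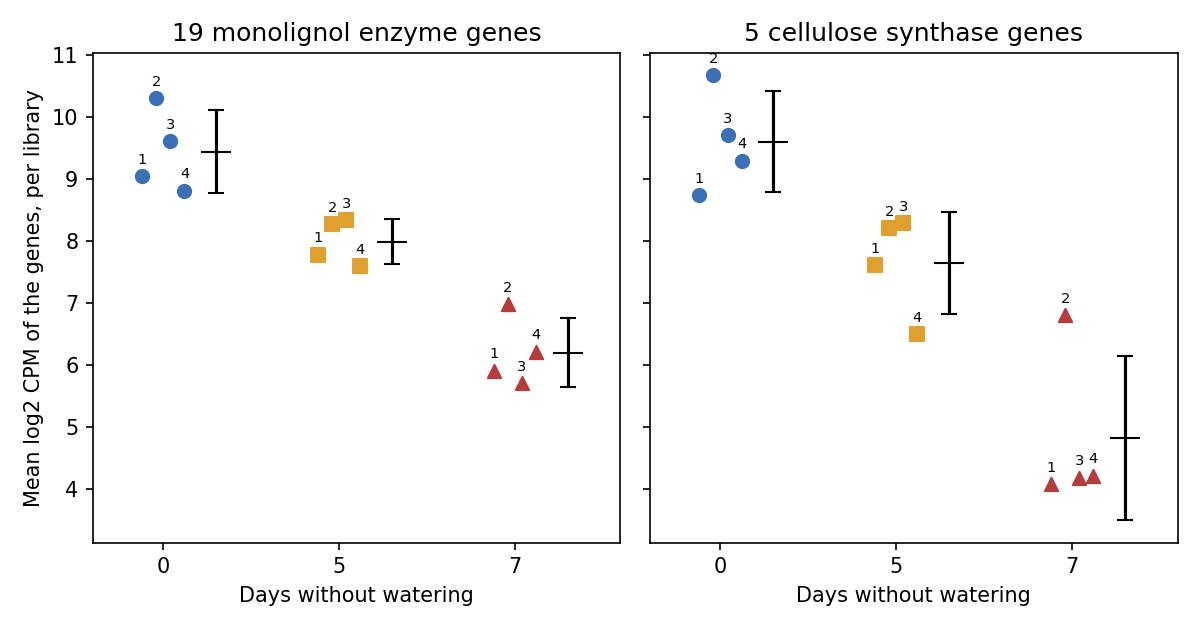
Mean log2 CPM of the 19 monolignol genes (left) and the 5 cellulose synthase genes (right) in each library by days without watering; points are libraries numbered by replicate, and black marks give the group mean with 1 SD. Cellulose synthase genes lay between 8.74 and 10.68 on day 0 and between 4.09 and 4.22 in 3 day 7 libraries, with day 7 replicate 2 at 6.80.

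Over all genes, 11344 of 26943 (42.1%) differed between day 7 and day 5, with 5995 higher and 5349 lower on day 7; 968 were higher and 821 lower against a minimum fold of 2. Potri.013G100900 had no count on day 5 and 12.9 CPM ± 23.1 (SD, n = 4) on day 7, at least 266-fold higher (edgeR adjusted p = 0.00874). Day 7 replicate 3 alone held 47.6 CPM, and without it the bound was 27.9-fold. Potri.019G090900 had no count on day 5 and 12.3 CPM ± 12.3 on day 7, at least 253-fold higher (at least 131-fold without day 7 replicate 3; edgeR adjusted p = 0.000645). Potri.006G019500 went from 7.92 CPM ± 10.3 to 0.0404 CPM ± 0.0807, with 2 counts on day 7 and a ratio of pooled counts of 217 (95% binomial interval 59.8 to 1798; edgeR adjusted p = 0.00101). This ratio was 71.9 without day 5 replicate 3 and at least 109 without day 7 replicate 4. Potri.006G097500 went from 21.7 CPM ± 28.4 to 0.136 CPM ± 0.141, with 7 counts on day 7 and a ratio of pooled counts of 165 (95% binomial interval 80.0 to 412; edgeR adjusted p = 0.00123). Without day 5 replicate 3, which held 63.5 CPM, the ratio was 51.7, and without day 7 replicate 4 it was 297; limma-voom did not call this gene (adjusted p = 0.116).

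Both drought days were then set side by side. On both days 4924 genes were higher than on day 0 and 4253 lower (4223 and 4460 with limma-voom), 9177 in all, and 591 were called in opposite directions. Independent lists of these sizes would share 2210.5 higher and 1832 lower genes and hold 4031 in opposite directions. Unchanged groups simulated against the same day 0 libraries shared 0, but with a mean of 0.05 edgeR calls per day (1197 on day 5 and 1208 on day 7 at an unadjusted p under 0.05) that 0 sets no measure for lists this long. With the day 0 libraries split 2 and 2, so that no library served both days, 6334 to 7352 genes were shared. Opposite calls then numbered 184 to 776. Across genes, which are not independent replicates, log2 fold changes of both days correlated at r = 0.831 with a covariance of 3.60, against 0.503 and 0.0725 in the simulation.

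Of the wood list, 16 of 24 genes were lower on both days and lower still on day 7, as were 582 genes overall. A further 706 genes were higher on both days and higher still on day 7. Changes on both days that were not told apart between days numbered 3327 higher and 3098 lower. By contrast, 4286 genes called on day 5 returned by day 7: they were no longer called against day 0 and differed from day 5 in the opposite direction. Of these, 1994 had been higher on day 5 and 2292 lower (2295 and 2078 with limma-voom). The higher ones had a median log2 fold change of 1.02 on day 5 and 0.037 on day 7. For the lower ones the medians were -1.04 and -0.0097. No wood gene was among the returned genes. Another 1540 genes were higher and 1102 lower on day 7, not called on day 5 and different from it; 4 wood genes were in the latter set.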

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

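The tests on day 7 replicates 2 and 3 were chosen after their values were seen; those on the return of day 5 changes, a pattern found in the data, and on other splits of the libraries were written before their own values were seen. A first test of an admixture in replicate 2, made on genes raised by drought, was replaced after its outcome was seen, because so small a share would lower such genes too little to decide. Of 44 groups of 4 libraries examined, 10 held a library far from the other 3 by Dixon's rule. Chance gives this in about 1 in 20 independent groups. Here groups share genes and libraries, and some hold genes picked for a jump, so the 10 cannot be set against that rate. Named genes were examined only in the groups of the comparison that names them, a limit set after a wider search had been seen.

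Wood genes stood apart in day 7 replicate 2. There the wood list took 0.470% of normalised counts, against 0.181% to 0.227% in the other day 7 libraries. The cellulose synthase genes took 0.0820% against 0.0103% to 0.0120%, with a mean log2 CPM of 6.80. The monolignol genes alone, at 0.388% against 0.169% to 0.216%, did not pass Dixon's rule, nor did the mean log2 CPM of the whole list, 6.94 against 5.39 to 5.80. A mislabelled library is argued against, since its Spearman correlation with another day 7 library (0.947) exceeded that with any library of another day (0.874). Depth is argued against by a total within 1.01 times that of another day 7 library. Admixed RNA of watered plants would need a share of 12.1%. For 236 other genes that nearly vanished in the 3 other libraries, this share was multiplied by their lowest day 0 CPM. Of these genes, 38.1% lay below 0.5 times that product, but their median was 0.732 times it (quartiles 0.244 and 1.56). The product is a low mark, since the share itself was derived from mean day 0 levels. Ratios to a product with the day 0 mean would be lower and were not computed. An admixture therefore stays open. So does a plant that responded less to the drought, which the labels give no means to test. Replicate 2 also had the largest wood share on day 0 (4.10% of normalised counts against 1.53% to 2.43%). On day 5 it did not (0.953% against 0.981% in replicate 3). A pairing of the replicate 2 libraries across days was not excluded either.

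A second pattern was a joint jump of 7 genes in day 7 replicate 3. Together they held 3.42% of its normalised counts (3.14% of its total count), against 0.226% to 0.249% in the other day 7 libraries. In day 5 replicate 4 they held 0.770% of normalised counts, against 0.243% to 0.302% in the other day 5 libraries. On day 0 their normalised share was 0.888% and 0.662% in replicates 1 and 4 and 0.286% and 0.271% in replicates 2 and 3. The between-day share of the variance of their level was 0.0312, but genes picked for a jump in 1 library have a low share by that choice, so a drought response stays open. Ratios among the 5 most abundant were nearly fixed across the 12 libraries (largest SD of a log2 ratio 0.193), so 1 source of reads counted for several gene models may account for these 5. Over all 7 genes the largest SD was 0.795, which argues against 1 source for all. The identity of these genes stays open, and without them 15810, 13764 and 11340 genes changed in the 3 comparisons.

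Changes of day 5 that shrank by day 7, in 4286 genes, made the third pattern. Extreme values picked by chance would shrink in other day 5 libraries too, yet 2022 returned genes picked with day 5 replicates 1 and 2 kept a median of 1.15 times their log2 fold change in replicates 3 and 4. Over the 6 ways of picking 2 libraries this share was 0.775 to 1.15, with a lowest quartile of 0.651. Over the 12179 genes called with replicates 1 and 2, returned or not, the median share kept was 1.05 in replicates 3 and 4. It was 0.723 on day 7, a difference of medians of 0.326 (0.224 to 0.375 over the 6 ways). A lone day 7 library close to day 0 is argued against, since 3698 genes or more returned when any 1 was left out. An early response that is relaxed as drought deepens is a candidate explanation, and plant age or harvest day is another, which the design confounds with drought.

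Other splits of the same 8 libraries into 4 and 4 did not give counts of changed genes like those observed. The share of 1 in 35, the smallest these libraries allow, argues against chance as their origin but cannot exclude it. Mixed splits hold the difference between days in their spread, so their adjusted counts are low whenever the days stand apart. The test does not tell drought from plant age or day of harvest. For day 5 against day 0, 1 of 35 splits, the real one, reached 15807 genes in edgeR, and the highest of the others was 0 (at an unadjusted p under 0.05, 4048 against 17059 for the real one). For day 7 against day 0, 1 of 35 reached 13761, and the highest of the others was 2 (5807 against 15363 unadjusted). For day 7 against day 5, 1 of 35 reached 11344, and the highest of the others was 30 (6935 against 13769 unadjusted).

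Drought effects differed between days 5 and 7 for the following results, each by the direct edgeR or fry test. The wood list was lower on day 7 than on day 5 by a median of -1.66 on the log2 scale, its monolignol part by -1.58 and its cellulose part by -2.38, though camera with an estimated correlation called none of them (p = 0.126, 0.122 and 0.18). Potri.012G006400 differed by -2.11 and Potri.019G130700 by -1.58. Potri.004G019400, without a count on day 5, was at 0.484 to 2.02 CPM on day 7, a log2 difference of at least 4.91. Potri.004G180200 and its neighbour Potri.004G180000, near 0 on day 5, each differed by 7.96, although day 7 replicate 2, at 0.478 CPM for both, lay below day 5 replicate 3 (0.810 CPM for both). Potri.005G013000, without a count on day 7, differed by -1.84 or more in size. Apart from these direct tests, 591 genes were called against day 0 in opposite directions on days 5 and 7.

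The remaining far libraries are given as values. Day 7 replicate 3 had 17.73 M counts, against 12.95 to 13.14 M in the other day 7 libraries. Potri.004G019400 was at 15.6 CPM in day 0 replicate 1 and at 12.4 to 12.8 CPM in the others of that day. Potri.013G100900 was at 47.6 CPM in day 7 replicate 3 and at 1.05 to 1.52 CPM in the others. Potri.006G019500 was at 23.4 CPM in day 5 replicate 3, with 2.21 to 3.23 CPM in the others, and at 0.161 CPM in day 7 replicate 4, with 0 in the others.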

How the results depend on the processing

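Leaving out the 7 jumping genes, the return of day 5 changes, and the parts and the count share of the wood list were examined only after the data were seen. Tested against a minimum fold of 2, 6062, 5623 and 1789 genes changed for day 5 against day 0, day 7 against day 0 and day 7 against day 5, fewer because the hypothesis is stricter; 7, 23 and 3 wood genes were then called. With an estimated correlation, camera did not call the wood list, at medians of -1.81, -3.56 and -1.66 (p = 0.294, 0.0704 and 0.126), with correlations of 0.626, 0.625 and 0.622 between members. Every other setting kept the 3 counts within 1.5 times. With 1 library left out they ranged from 14471 to 15284, 12241 to 13806 and 9098 to 11682. DESeq2 called 16610, 14735 and 12632. With a replicate block the counts were 15206, 13095 and 10757. Replicate numbers did not pair the libraries throughout: 4 of 12 correlations between same-numbered libraries were over 0.1 (range -0.171 to 0.487). Replicate 2 exceeded the highest correlation with another number in each comparison: 0.0536 against 0.0131, 0.125 against 0.0184 and 0.487 against -0.0897. A pairing of the replicate 2 libraries was therefore not excluded. Upper-quartile scaling lowered the share of higher genes to 46.2% on day 5 and 48.7% on day 7. No wood gene was called higher in any setting. Of 300 values of named genes under other settings, 297 kept their call; limma-voom lost Potri.004G180200, Potri.004G180000 and Potri.006G097500, and the cause was not tested. A further 6 had no value: DESeq2 gave no adjusted p for Potri.013G100900 and Potri.006G019500, and Potri.004G180200 and Potri.004G180000 were filtered out at 1 CPM in 4 libraries and with the 2 compared groups alone. Depth limits the genes at 0, whose folds are given as bounds. Of simulated 2-fold changes edgeR recovered 22% to 36% and DESeq2 61% to 66%, the latter with more false calls. Far fewer genes changed in those simulations than were called here, so these shares do not measure what was missed in the data.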

Other observations

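The tests of regulators and of adjacent pairs were written after the results of the report but before their own values were seen, while the tests without similar pairs, of runs and of identical counts were added after the share of adjacent pairs was known. The list of regulators was chosen after those results and, like the wood list, rests on published designations that the files do not give.

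Published NAC and MYB regulators of the secondary wall, transcription factors that switch on wood synthesis genes, were lower in drought, as the wood list was. Of 8 such genes, 4 NAC and 4 MYB, 6 were lower on day 5 and 7 on day 7, with a median log2 fold change of -2.18 and -3.63. Whether these regulators fell on balance, without regard to the wall enzymes, was tested with limma's fry, which gave adjusted p = 0.000115 on day 5 (7.65e-05 unadjusted) and adjusted p = 0.000109 on day 7 (3.62e-05 unadjusted). With an estimated correlation camera gave p = 0.127 and p = 0.0786. Between day 5 and day 7 only 2 of the 8, both MYB genes, were lower (limma fry adjusted p = 0.0703 over 3 tests). The 4 NAC genes had already changed by -2.10 to -4.45 on day 5 and differed from there by 0.48 to -1.33 on day 7, none past the edgeR threshold. The least expressed of the 8, a MYB gene at the 19.4th percentile of day 0, was not called on any day.

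Genes next to each other tended to change in the same direction. Of 5318 adjacent pairs with both members called on day 7 against day 0, in the order of their identifiers, 67.7% shared a direction, against 50.4% on average and at most 52.7% in 1000 shuffles within chromosomes. The hypothesis that neighbours are co-expressed or share reads predicted such an excess. Without pairs whose log2 ratio varied by an SD under 0.3 across libraries, 64.6% of 4842 pairs still shared a direction. Pairs with nearly fixed ratios therefore do not make up all of the excess. Pairs that share only part of their reads can vary more and stay in, so the filter cannot tell co-expression from shared reads. On day 5 the values were 64.8% of 6827 pairs and 61.1% of 6173.

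Runs of at least 4 adjacent genes, all changed at least 2-fold by point estimate in 1 direction, numbered 131 on day 5 and 104 on day 7, against at most 29 and 24 in 100 shuffles. In each comparison the longest held 16 genes, from Potri.001G103000 to Potri.001G104500, chosen here after its values were seen. All 16 were higher, with a median log2 fold change of 2.33 on day 5 and 3.47 on day 7. Genes of this stretch have identical or nearly identical counts in part, so its length in independent genes is not known. Counting each set of identical genes once left 15785, 13745 and 11334 changed genes in the 3 comparisons of the report.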
